A study of Homo sapiens with 4 samples.

How the data were processed

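The data are AGO1 iCLIP libraries from human microvascular endothelial cells, 2 from hypoxia and 2 from normoxia, grouped by the titles in the labels. Per the labels' protocols, RNA was reverse transcribed, and the cDNA was selected by size, circularized, linearized and amplified. Each sample has 2 deposited tables, marked H and L. The labels do not say what the marks stand for, so both were summed into 1 library per sample. The mix was unequal: the L table gave 87.8% of the named counts in hypoxia replicate 1, 38.5% in hypoxia replicate 2, and 39.5% and 24.7% in normoxia replicates 1 and 2. Across genes the H and L tables of a sample correlated at r between 0.896 and 0.965 on the log2 CPM scale. The design text of the series calls the replicates biological.

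Each deposited table lists 174387 transcripts with a length, an effective length, an estimated count and a TPM. Per the submitters' processing notes the genome build is hg38. The aligner, the counter and the handling of duplicate or multiply aligned reads are not given in the sources used here. The column of estimated counts that the authors deposited holds whole numbers only and was used as raw counts. The deposited TPM column is 0 in every row and was not used, and the effective length equals the length in every row. The deposited length is the genomic span of the transcript, introns included: 94.65% of the 3064 spans of 300 kb or more matched an annotated transcript span exactly, against 1.37% after a shift of 13 bp. A read therefore appears in every transcript that spans it. Among 17782 pairs of nested transcripts, the inner one was at or below the outer one in all 8 tables in 99.9%, against 41.0% when the inner one was replaced by a random one of like span. The sums of the tables are thus not numbers of reads. The counting followed strand: among nested genes on the same strand 99.8% of 421 pairs were ordered in this way, against 18.5% of 238 pairs on opposite strands. Genes that overlap on the same strand share reads.

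The tables identify transcripts by UCSC identifiers and do not pair them with gene names. Names were assigned by matching each span to transcripts of GENCODE release 29 (GRCh38) and scoring how well the counts of the candidate transcripts of a gene nested inside each other. A name needed a score of at least 2 (log10 units) and a margin of 1 over the next gene, or a span of at least 40000 bp that matches a single transcript (10000 bp with a nested partner). Further transcripts were added to genes named in this way at a lower minimum score and the same margin. They stand for 644 of the genes, among them OAF, ADAMTSL4, ANK1, HEMGN and ZBTB37, and no rate of false names from shifted spans was estimated for them. Transcripts with fewer than 200 counts over all tables were not matched, a floor that favours genes present in the deeper normoxia libraries. This named 10439 genes, 9513 of them protein-coding. With all spans shifted by 13 or -29 bp, the number of genes named by nesting was 0.663% of the real one, an estimate of false names. This estimate does not carry over to single spans. Transcripts named by a single span alone numbered 3503 and 3444 with the shifts, against 1844 without. Their estimate of 0.931% false scales the shifted matches by the estimated share of spans whose true transcript is not annotated. As a check that used no identifier in the naming, 99.15% of 2122 transcripts used for the genes had a named transcript with a neighbouring identifier on the same chromosome, against 10.5% by chance. The check covered only the newest series of identifiers. Genes with an older identifier, among them SLCO5A1, SORBS2, IFITM2, HMGA1 and BACE2, were not checked in this way. The score and margin were set after looking at several settings, at which genes they named and at this check. A second setting (score 1.5, margin 1.5), which named 10829 genes with an estimated 1.67% false, was used for a time because genes such as some endothelial markers were unnamed, and the gene tests were run under both. The first setting was then restored for its lower rate of false names, and the second is kept as an alternative. Among the transcripts left without a name are some of the most abundant. Of the 20 most abundant of them, 5 have a span that matches no gene, uc001sun.6 has one that matches only RGPD1, and the others match several genes.

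Tests were fixed before the data were examined, with departures named here. The plan was to sum the transcripts of each gene. Because nested transcripts repeat the same reads, the 1 named transcript with the most counts stands for its gene, and the sum is an alternative. The counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, glmQLFit and glmQLFTest, condition as the only term), and 10273 genes passed the filter. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F. The common biological coefficient of variation was 0.885 with 2 residual degrees of freedom. CPM values use the TMM-scaled totals of named-gene counts, with normalization factors from 0.92 to 1.07. Gene lists were tested with camera (limma 3.58.1, log2 CPM with a prior count of 2, correlation 0.01), with an estimated correlation and fry as alternatives. Shares of counts were compared by exact two-sided permutation tests.

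The test was tried on simulated counts, with seeded sets of genes changed by known folds. It was first run with the common dispersion of 0.783 for every gene, where none of the changed genes was recovered at any fold. A second version with the dispersion that follows abundance (median 0.574) was added after that outcome was seen, and both are given. At a dispersion of 0.05, as a check of the code, 40%, 96%, 98% and 100% of 2-, 4-, 8- and 16-fold changes were recovered, with 7 false calls among 10273 genes.

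Genes are named by a rule fixed beforehand: in each direction 12 genes, those past the adjusted threshold with the largest change or, in their absence, those with the smallest unadjusted p, a mean of at least 5 CPM in the higher group and both hypoxia samples on one side of both normoxia samples. Up to 4 members of each list with the smallest p and the 10 most abundant genes are named too, and a few genes that this rule takes are not reported here. Alternatives covered the normalization (relative log expression factors, RLE, in edgeR), the filter, the test (DESeq2 1.42.0, limma-voom), the files, the most abundant genes and a replicate block. Each library was also left out in turn, in which case the lone sample is assumed to vary like the other group. The lists of mitochondrially encoded transcripts and small structural RNAs had no named member and were not tested. The fixed markers of leukocytes and erythroid cells had no tested member, and the other cell type markers are given among the other observations.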

Results

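AGO1-bound RNA was measured by individual-nucleotide resolution crosslinking and immunoprecipitation (iCLIP) in human microvascular endothelial cells, the cells that line small blood vessels. AGO1 is one of the Argonaute proteins, which carry microRNAs to their target RNAs. In iCLIP, ultraviolet light joins a protein to the RNA it touches, an antibody pulls the protein down, and the attached RNA is sequenced. The series holds 4 samples, 2 from cells kept at 2% oxygen (hypoxia) and 2 from cells kept at 20% oxygen (normoxia), described by the submitters as biological replicates. The protocol lists exposures of 12, 24 and 48 h, and the labels do not say which exposure each sample had. No sample without the antibody, and no measure of total RNA from the same cells, was used here, so a difference below is a difference in counts recovered with AGO1 and not in RNA abundance or in binding taken alone.

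The counts of 10439 genes that could be named came to 34093360 and 12643041 in hypoxia replicates 1 and 2, and to 44682835 and 51593437 in normoxia replicates 1 and 2. These counts cover the whole genomic span of each transcript, introns included. Of the named genes, 505 and 643 had no count in the hypoxia libraries, against 70 and 28 in the normoxia libraries. After every library was thinned to 12643041 counts, the numbers of genes at 0 were 781 and 643 in hypoxia and 146 and 63 in normoxia. Across genes, the log2 CPM (counts scaled to a common library total) of the normoxia replicates correlated at r = 0.798, and that of the hypoxia replicates at r = 0.678. Between conditions r ranged from 0.692 to 0.717, so the hypoxia libraries were no closer to each other than to the normoxia libraries. These correlations are across genes, which are not independent replicates. A count of 0 allows up to 3 counts, which is 0.0957 and 0.242 CPM in the hypoxia libraries and 0.0629 and 0.0561 CPM in the normoxia libraries. Reads amplified by PCR are not independent molecules, so such limits and the counting intervals below cover counting error only.

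Most of the named counts recovered with AGO1 came from protein-coding genes in both conditions. The naming bears on this, since it needs nested transcripts or a long span, and 9513 of the 10439 named genes were protein-coding. Abundant short transcripts, such as uc031uup.1 with a span of 164 bp, have no name. The shares below therefore describe the named genes and not all RNA recovered. Protein-coding genes took 96.7% ± 0.553 of the named counts in hypoxia and 96.8% ± 0.388 in normoxia (mean ± SD, n = 2 each), and the difference was smaller than the spread between replicates. Long non-coding genes took 3.23% ± 0.546 in hypoxia and 3.15% ± 0.377 in normoxia. Pseudogenes and other classes took 0.0765% ± 0.00712 and 0.0919% ± 0.0106, lower in both hypoxia libraries than in both normoxia libraries. The 10 most abundant genes of each library held 2.87% ± 0.443 of the counts in hypoxia and 2.90% ± 0.476 in normoxia, so no small set of named genes dominated a library. The exact two-sided permutation test gave p = 1 for the protein-coding and long non-coding shares, 0.333 for the pseudogene share and 0.667 for the top 10 genes, and cannot go below 0.333 with 2 samples against 2.

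The 10 genes with the largest share over all 4 libraries were HFM1, APP, AHNAK, APLP2, DOCK4, UTRN, MBNL1, PDE3A, HSPG2 and ZEB1. HFM1, a helicase known from meiosis, held 0.429% of the counts pooled over libraries of unequal depth. Its count covers a span of 144104 bp, introns included, and where in that span the reads lay was not examined. Of these 10 genes AHNAK had the largest share in hypoxia replicate 1 (0.49%), UTRN in hypoxia replicate 2 (0.318%) and HFM1 in both normoxia libraries. HFM1 was at 2362 ± 650.0 CPM in hypoxia and 5009 ± 1248 in normoxia (mean ± SD, n = 2 for these and all CPM values below). APP, the amyloid precursor protein, was at 3607 ± 644 and 3732 ± 694 CPM. HSPG2, which encodes the basement membrane proteoglycan perlecan, was at 2758 ± 1816 CPM in hypoxia and 1818 ± 265 in normoxia. AHNAK, a large scaffold protein, was at 3619 ± 2419 and 2152 ± 294 CPM. ZEB1, a transcription factor, and DOCK4, a guanine nucleotide exchange factor, differed by a log2 fold change of 0.29 ± 0.40 and 0.27 ± 0.40 (± SE). PDE3A, a cyclic nucleotide phosphodiesterase, had -0.99 ± 0.56, and UTRN, the cytoskeletal protein utrophin, had 0.50 ± 0.40. The splicing regulator MBNL1 and the APP relative APLP2 had 0.10 ± 0.41 and -0.09 ± 0.50. None of these 10 genes passed the adjusted threshold in edgeR, and HFM1 passed it in limma-voom, as lower in hypoxia.

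The design asks which RNAs differ in their recovery with AGO1 between 2% and 20% oxygen. No gene passed an adjusted p of 0.05 among the 10273 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment), and the smallest adjusted p was 0.117. At an unadjusted p under 0.05 there were 748 genes, 274 higher and 474 lower in hypoxia, where chance alone would give about 514. DESeq2 called 213 genes at an adjusted p of 0.05, 60 higher and 153 lower, and limma-voom called 11, of which 9 were higher. Without hypoxia replicate 1 the edgeR test called 36 genes and without hypoxia replicate 2 it called 140. In counts simulated for this comparison, with 10221 genes tested, the test recovered no 2-fold change, 12.2% of 4-fold, 36.0% of 8-fold and 55.1% of 16-fold changes when the spread followed the trend estimated over genes. When the spread was set to the common estimate for all genes (10268 tested), it recovered no change of any of these sizes. A change of a few fold was therefore mostly not detectable with these libraries.

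The genes at an unadjusted p under 0.05 were split by abundance. Among the 3424 genes with the lowest mean CPM, 347 such genes were lower in hypoxia and 34 higher. Among the 3424 genes in the middle, 53 were lower and 56 higher, and among the 3425 most abundant genes 74 were lower and 184 higher. Of the 474 lower genes, 120 had no count in either hypoxia library and 270 had none in at least 1 of them, while of the 274 higher genes 3 had no count in at least 1 normoxia library.

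**Figure D1:**
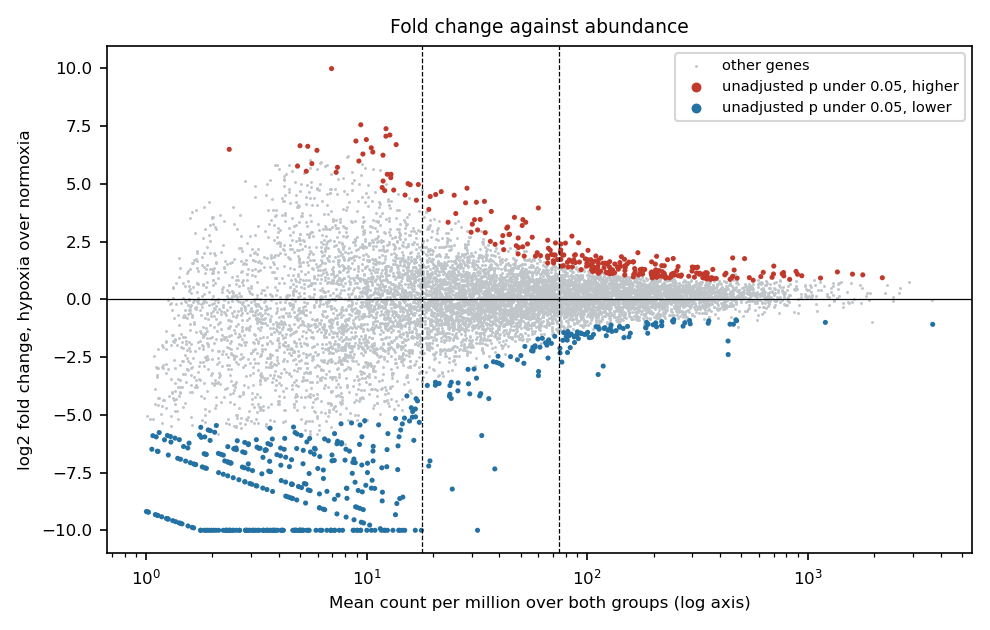
Log2 fold change of hypoxia over normoxia against the mean CPM of both groups (log axis) for each of the 10273 genes tested. Red and blue points are the 274 higher and 474 lower genes at an unadjusted p under 0.05, values beyond -10 or 10 are drawn at those limits, and dashed lines part the genes into 3 equal groups by mean CPM, of which the lowest holds 347 of the lower genes.

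The genes below are those with the smallest unadjusted p in each direction, and none of them passed the adjusted threshold. SLCO5A1, a member of the organic anion transporter family, gave the smallest p. It lies on the minus strand of chromosome 8 from 69672343 to 69833390 (GRCh38), and it was at 139.5 ± 0.356 CPM in hypoxia and 732 ± 88.0 in normoxia, a log2 fold change of -2.39 ± 0.40 with an adjusted p of 0.117 by edgeR. IFITM2, an interferon-induced membrane protein on chromosome 11 (307927 to 309392, plus strand), was at 28.1 ± 0.744 CPM in hypoxia and 208 ± 35.5 in normoxia, 7.42 times as high in normoxia. IFITM2 has near-identical neighbours, and how the authors treated reads that match several places is not given in the sources used here, so its value is uncertain. HMGA1, a chromatin architectural protein, was at 194 ± 52.1 and 677 ± 106 CPM, a log2 fold change of -1.81 ± 0.40, and like PABPC1 and GAPDH below it has processed pseudogenes that can share its reads. SORCS2, a sortilin-related receptor, was at 21.2 ± 17.6 CPM in hypoxia, and its normoxia mean of 203 came with an SD of 212.

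Several of the lower genes were close to absent from both hypoxia libraries. LINC02476, a long intergenic non-coding RNA, had 2 counts in hypoxia and 6413 in normoxia, a ratio of 1387 with an exact 95% counting interval from 384 to 11456, or 1987 and 787 against hypoxia replicates 1 and 2 alone. ADAMTSL4, a secreted matrix-associated protein, had no count in hypoxia and 35.4 ± 10.3 CPM in normoxia, at least 210.0-fold lower against a floor of 3 counts per library. On the same floor EMP3, an epithelial membrane protein, was at least 197-fold lower, HEMGN 167-fold, ZBTB37 172-fold, and PKMYT1, a kinase that inhibits CDK1, 166-fold. PKMYT1 was at 27.9 ± 21.2 CPM and EMP3 at 33.2 ± 23.1 CPM in normoxia, so the normoxia replicates differed as well. The spread was widest for ZBTB37, at 6.84 and 51.2 CPM in normoxia replicates 1 and 2, whose bound was 40.5-fold against replicate 1 alone and 303-fold against replicate 2 alone. The same bounds were 100.1 and 294 for EMP3, and 76.7 and 254.5 for PKMYT1. ANK1, which encodes an ankyrin of the membrane skeleton, was at 0.152 ± 0.101 CPM in hypoxia and 48.7 ± 17.5 in normoxia, and its annotated span also holds the microRNA gene MIR486-1. The non-coding gene AC069277.1 was at 0.4995 ± 0.661 and 75.7 ± 4.36 CPM. The fixed erythroid and leukocyte markers had no tested member, so whether RNA of such cells contributed to these genes was not tested. With the L tables alone, the 4 genes past the adjusted threshold in edgeR, all lower, were LINC02476, AC069277.1, HBE1 and ANK1. With transcripts summed, the 1 such gene was MYB, also lower.

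The genes on the higher side had counts in every library. SORBS2, an adaptor protein of the actin cytoskeleton on chromosome 4 (185585444 to 185956368, minus strand), was at 709 ± 53.4 CPM in hypoxia and 205 ± 4.67 in normoxia, a log2 fold change of 1.79 ± 0.39 with an adjusted p of 0.404 by edgeR. BACE2, an aspartyl protease, was at 1025 ± 22.9 and 378 ± 17.1 CPM, and OAF at 272 ± 11.1 and 67.3 ± 9.21 CPM. FAM155A, an auxiliary subunit of a sodium leak channel, was at 799 ± 233 and 236 ± 57.7 CPM. FAM155A-IT1, at 148 ± 40.9 and 22.3 ± 11.8 CPM, is annotated within FAM155A on the same strand, so the counts of both cover some of the same reads. ARHGAP10, a GTPase-activating protein, had a log2 fold change of 1.86 ± 0.44, RIN3, an exchange factor for Rab5, had 1.52 ± 0.44, and the pseudokinase PRAG1 had 1.38 ± 0.40. LINC01134 was at 113 ± 64.7 CPM in hypoxia and 7.28 ± 4.00 in normoxia. FBXO25, an F-box protein, was at 95.8 ± 13.9 and 9.50 ± 7.19 CPM, and RGS7, a regulator of G protein signalling, at 86.2 ± 57.8 and 7.36 ± 1.16. The non-coding gene AC013652.1 was at 155 ± 22.5 and 28.3 ± 10.7 CPM. DESeq2 called all 24 of these genes at an adjusted p under 0.05, and limma-voom called 4 of them.

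**Figure D2:**
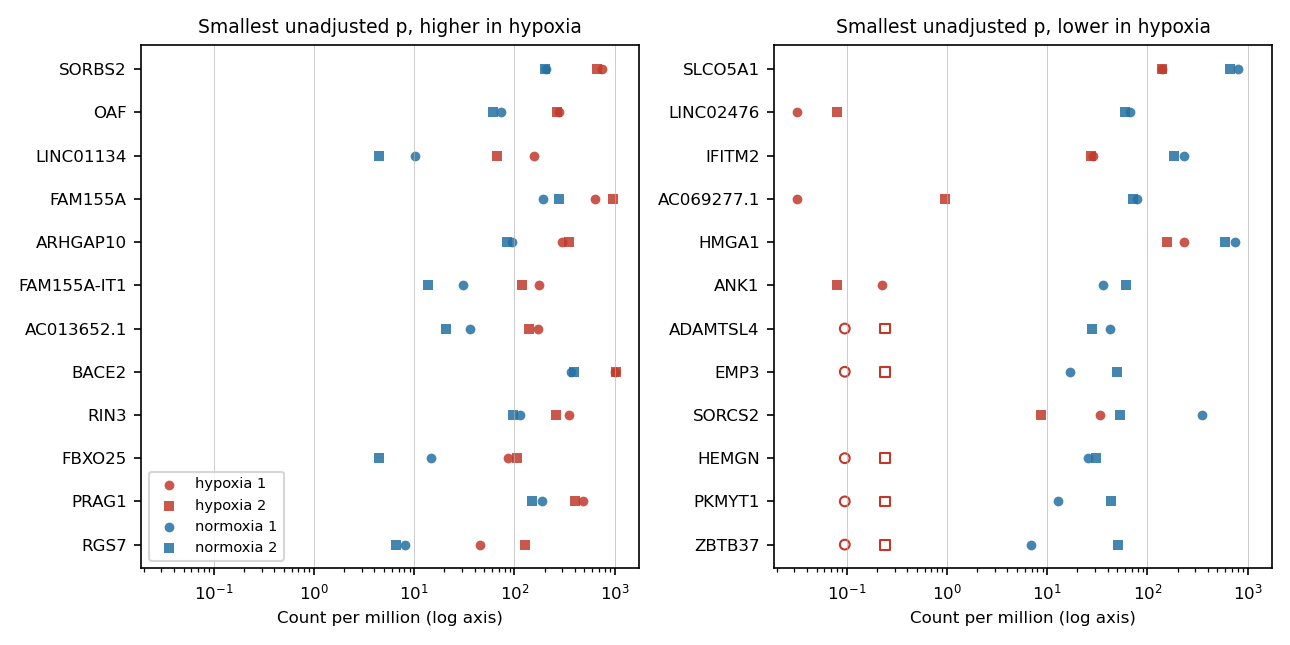
CPM (log axis) in each of the 4 libraries for the 12 genes with the smallest unadjusted p in each direction. Filled red points are hypoxia, filled blue points are normoxia, circles are replicate 1 and squares replicate 2, and open points mark libraries with no count, drawn at the level of 3 counts. SLCO5A1 sits at 139.5 CPM on average in hypoxia and 732 in normoxia, and 5 of the lower genes have no count in either hypoxia library.

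Of the 21 gene lists fixed before the data were examined, 19 had at least 3 tested members and 2 stood apart from other genes in camera with a preset correlation of 0.01. Many fixed symbols had no tested gene, among them KDR, CDH5, CA9 and BNIP3. Tested were 19 of 36 symbols for cell cycle, 10 of 17 for cholesterol synthesis and 36 of 49 for the HIF-responsive list. For angiogenic signalling it was 15 of 35, and for endothelial identity 14 of 26. The cell cycle list was lower in hypoxia (adjusted p = 0.00187), with 16 of its 19 tested members lower and a median log2 fold change of -1.27. With an estimated correlation between its genes the adjusted p was 0.831. Without hypoxia replicate 1 and without normoxia replicate 1 it was 0.0789 and 0.121, and over the alternatives it ranged from 1.43e-05 to 0.831. The median was -2.67 without hypoxia replicate 2. Of the fixed markers of other cell types, all 4 tested epithelial ones had a negative log2 fold change, among them EPCAM (-3.45 ± 2.28) and CDH1 (-3.09 ± 2.35), as had the smooth muscle and pericyte markers MYH11 (-4.49 ± 2.46) and NOTCH3 (-5.28 ± 2.68), while ACTA2 had 0.70 ± 1.47. Of the 4 tested lymphatic endothelial markers 3 were lower and 1 higher, and the 1 tested fibroblast marker was higher. None of these markers passed. EPCAM, CDH1, MYH11 and NOTCH3 belong to the third of genes with the lowest mean CPM, where the median log2 fold change over all genes was -0.75. UBE2C, a ubiquitin-conjugating enzyme of mitotic exit, had 2 counts in hypoxia and 2861 in normoxia, a ratio of 619 with an exact 95% counting interval from 171 to 5112. Both counts lay in hypoxia replicate 2, and against that library alone the ratio was 175.5. AURKB, a mitotic kinase, had no count in hypoxia and 7.36 ± 7.98 CPM in normoxia, at least 43.6-fold lower, or 77.1-fold and 10.2-fold against normoxia replicates 1 and 2 alone. RRM2, a subunit of ribonucleotide reductase, was at 3.37 ± 4.76 CPM in hypoxia and 61.8 ± 16.2 in normoxia. CENPE, a kinetochore motor, was at 24.6 ± 32.8 and 81.6 ± 27.1 CPM. The mean log2 fold change of the list was -2.19, and -1.90 with AURKB at its bound. No member passed the adjusted threshold over all genes or adjusted over the list alone, and 3 members, all lower, were at an unadjusted p under 0.05.

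The cholesterol synthesis list was higher in hypoxia (camera adjusted p = 0.0364), with 9 of 10 tested members higher and a median log2 fold change of 0.88. With an estimated correlation the adjusted p was 0.831, without hypoxia replicate 1 it was 0.587, and without normoxia replicate 2 it was 0.262, in a range over the alternatives from 0.000803 to 0.831. The list also did not pass with transcripts summed (camera adjusted p = 0.118) or with nested names only (0.139), so its call depends on the naming step as well. STARD4, a sterol carrier, was at 238 ± 0.898 CPM in hypoxia and 110.0 ± 42.0 in normoxia. DHCR7, which catalyses the last step of cholesterol synthesis, was at 59.1 ± 12.6 and 13.6 ± 8.85 CPM. SREBF2, the transcription factor that controls these genes, was at 312 ± 237 CPM in hypoxia and 159.7 ± 28.96 in normoxia, and its annotated span also holds MIR33A. Without hypoxia replicate 1 the log2 fold change of SREBF2 was -0.14 and 6 of the 10 members were higher, with a median of 0.43. No member passed the adjusted threshold, over all genes or adjusted over the list alone.

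The HIF-responsive list, genes known to be induced by hypoxia-inducible factors, did not pass (camera adjusted p = 0.972). Of its 36 tested members, 19 were higher and 17 lower, with a median log2 fold change of 0.06 and a mean of -0.28. LDHA, lactate dehydrogenase A, had the smallest p of the list and was at 83.3 ± 3.56 CPM in hypoxia and 230 ± 34.3 in normoxia. HILPDA, a lipid droplet protein, had 1 count in hypoxia and 842 in normoxia, a ratio of 364 with an exact 95% counting interval from 65.2 to 14403. Its normoxia counts were 776 and 66 in replicates 1 and 2, and against each alone the ratio was 712 and 54.0. MXI1 was at 3.71 ± 5.12 and 44.4 ± 5.39 CPM. NDRG1 was at 170 ± 15.1 CPM in hypoxia and 77.2 ± 9.69 in normoxia. Of the 19 tested glycolysis genes, 9 were higher and 10 lower, with a median of -0.28 and a camera adjusted p of 0.763. PFKFB4 was at 0.943 ± 1.29 and 17.8 ± 16.1 CPM, ALDOA at 79.4 ± 6.11 and 131 ± 42.5, and GAPDH at 267 ± 43.7 and 177 ± 86.5. No member of either list passed the adjusted threshold, over all genes or adjusted over the list alone.

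Endothelial genes were recovered with AGO1 in both conditions, and most had a positive log2 fold change. In the angiogenic signalling list 11 of 15 tested members were higher, with a median of 0.46, and in the endothelial identity list 12 of 14 were, with a median of 0.33. Neither list passed (camera adjusted p = 0.236 for both). Most of these members belong to the third of genes with the highest mean CPM, where the median log2 fold change over all genes was 0.167. No matched random lists were drawn for these 2 lists, so a lean beyond that of abundant genes was not tested by matching. PGF, the placental growth factor, was at 245 ± 98.7 CPM in hypoxia and 79.5 ± 63.9 in normoxia. FLT4, a receptor for vascular endothelial growth factors C and D, was at 197 ± 115 and 79.8 ± 29.5 CPM. ENG, the co-receptor endoglin, was at 482 ± 175 and 252 ± 59.8 CPM, and NRP2 at 1173 ± 402 and 773 ± 320. ERG, a transcription factor of endothelial cells, was at 822 ± 41.8 and 522 ± 52.2 CPM, a log2 fold change of 0.66 ± 0.38. The junction proteins ESAM and CLDN5 had 0.97 ± 0.49 and 0.78 ± 0.61, and the surface protein EMCN had 0.46 ± 0.42. No member of either list passed, over all genes or adjusted over the list alone.

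Among genes of the microRNA pathway and mRNA decay, 9 of 27 tested members were higher and 18 lower, with a median of -0.33 (camera adjusted p = 0.769). PABPC1, the poly(A)-binding protein, was at 332 ± 10.2 CPM in hypoxia and 614 ± 44.3 in normoxia, a log2 fold change of -0.89 ± 0.38. DDX6, a decapping-associated helicase, had -0.68 ± 0.42, PAN3, a subunit of a deadenylase, 0.60 ± 0.38, and EDC4, a decapping scaffold, 1.52 ± 1.01. The fry test for change in either direction gave this list an adjusted p of 0.000921, and its test for change on balance in one direction gave 0.747. The fry tests do not compare a list with other genes.

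The 5 lists of known microRNA targets did not pass, and no member of them passed the adjusted threshold. For let-7 targets 9 of 18 tested members were higher, with a median of 0.00 (camera adjusted p = 0.769), and IGF2BP1, an RNA-binding protein, was at 14.8 ± 11.3 CPM in hypoxia and 50.4 ± 9.85 in normoxia. FIGN and INSR of that list had log2 fold changes of -2.07 ± 1.602 and 0.67 ± 0.54. For targets of miR-210, the microRNA known to be induced by hypoxia, 11 of 18 were higher with a median of 0.14 (camera adjusted p = 0.763). UBQLN1 of that list was at 124 ± 12.7 and 248 ± 22.8 CPM, P4HB at 84.8 ± 9.27 and 169.6 ± 1.57, PTPN1 at 299 ± 76.6 and 199.9 ± 65.1, and E2F3, also a miR-17-92 target, at 291 ± 115 and 191 ± 8.77. For miR-126 targets 3 of 5 were higher, and SLC7A5, an amino acid transporter, had a log2 fold change of 1.12 ± 0.61 while SPRED1, an inhibitor of Ras signalling, had -0.35 ± 0.38, TOM1 0.68 ± 1.13 and CRK 0.08 ± 0.59. For miR-17-92 targets 8 of 11 were higher with a median of 0.29, and ZNFX1, MAPK9 and ITGA5 had 1.01 ± 0.55, 1.04 ± 0.64 and 0.64 ± 0.47. For miR-21 targets 6 of 11 were higher with a median of 0.04, and TGFBI had 0.88 ± 0.50, TPM1 0.73 ± 0.54 and PPARA -1.32 ± 1.08. The camera adjusted p of the last 3 lists was 0.763, 0.256 and 0.763, and no member of the 5 lists passed adjusted over the list alone.

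**Figure D3:**
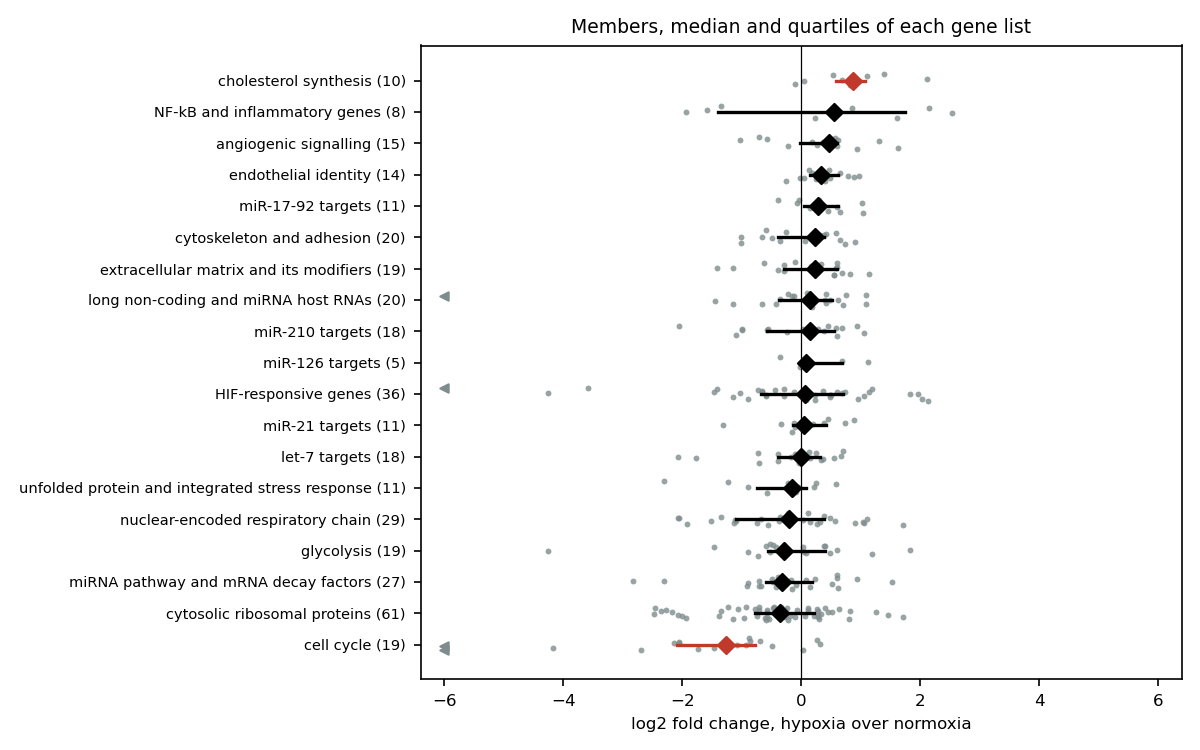
Log2 fold change of hypoxia over normoxia for every tested member (grey points, with arrowheads at the left edge for values beyond the axis), the median (diamond) and the quartiles (bar) of each of the 19 gene lists, with the number of tested members in brackets. Lists in red passed camera at an adjusted p of 0.05 with the preset correlation. The cell cycle list has a median of -1.27 and the cholesterol synthesis list of 0.88, while the HIF-responsive list centres on 0.06.

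Long non-coding and microRNA host RNAs went both ways, with 11 of 20 tested members higher and a median of 0.14 (camera adjusted p = 0.763). H19 had 2 counts in hypoxia and 769 in normoxia, a ratio of 166 with an exact 95% counting interval from 45.9 to 1376. Its normoxia counts were 93 and 676 in replicates 1 and 2, and against each alone the ratio was 42.7 and 276.6. CYTOR was at 537 ± 128 and 319 ± 100.4 CPM. ZFAS1, at 328 ± 121 CPM in hypoxia and 154 ± 65.7 in normoxia, hosts several small nucleolar RNAs within its span. SNHG16, another such host, was at 51.0 ± 27.4 and 113 ± 71.0 CPM. No member passed, over all genes or adjusted over the list alone. For 7 of the 19 lists, the HIF-responsive, let-7, miR-210, miR-21, long non-coding, inflammatory and cytoskeletal ones, the median differed in sign from a mean or from the test.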

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

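The test of the cell cycle list median with 1 library left out was chosen after the values it measures had been seen.

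A signal outside the named genes was higher in both hypoxia libraries than in both normoxia libraries for 2 of the 20 most abundant transcripts without a name, and lower in both for 5 of them, whose ratios of hypoxia to normoxia ran from 0.0756 to 0.83. Among the higher ones, the transcript uc032wyd.2, with a span of 331 bp that matches many annotated transcripts, was at 4676 ± 479.6 CPM (relative to the named counts) in hypoxia and 2868 ± 351 in normoxia (mean ± SD, n = 2). The transcript uc021zba.3, with a span of 496640 bp, was at 1879 ± 210.4 and 1263 ± 90.0.

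More genes were lower than higher in hypoxia at an unadjusted p under 0.05, 474 against 274, and of the lower genes 120 had no count in either hypoxia library. Depth at the stage of testing is argued against as the only cause, since after thinning all libraries to the shallowest the share of lower genes was 63.6% (median of 20 thinnings, range 62.6 to 64.8%). The genes and their transcripts were chosen on the full counts, so thinning does not remove depth that acted through that choice. The excess lay among low genes: 347 of 381 such genes were lower among the genes with the lowest mean CPM, 53 of 109 in the middle group, and 74 of 258 in the highest of 3 equal groups, and the floor of 200 counts for naming, which favours genes present in the deeper normoxia libraries, could add to this. The last share, 28.7% (exact 95% binomial interval 23.2 to 34.6%), shows no excess of lower genes where counts are high. Fewer distinct molecules in the hypoxia libraries, which would put low genes at 0, would give such a pattern. So would any other cause that acts on low genes, in either condition, so this share does not single it out. Whether the 184 higher genes of that group have the same source was not tested. CPM values are relative, and the median log2 fold change was 0.167 over all genes of that group and -0.75 in the lowest group. Between the hypoxia replicates 2.49% and 3.57% of genes were at 0 where at least 20 counts were expected from the other replicate, against 0.446% and 0.208% between the normoxia replicates, while between the tables of 1 sample the share was not higher in hypoxia throughout (0 to 1.10%, against 0 to 0.495% in normoxia), and a biological loss of low AGO1-bound RNAs in hypoxia stays open, as untested.

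The cell cycle list had a median log2 fold change of -1.27, at percentile 0.03 of 10000 random lists matched on mean CPM and span, whose medians ranged from -0.69 to 0.62 (central 95%). Loss of low genes in general is argued against by that value, since the matched lists carry it too. One library as the cause of the direction is argued against, since the list median with 1 library left out ran from -2.67 to -0.90, but the list did not pass without hypoxia replicate 1 (adjusted p = 0.0789) or without normoxia replicate 1 (0.121). The matched lists hold unrelated genes, and with an estimated correlation of its own members the list did not pass (adjusted p = 0.831). A difference in the number of cycling cells between the cultures, in RNA from other cells, in RNA abundance or in AGO1 binding stays open, and no value here separates them.

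The cholesterol synthesis list had a median of 0.88, at percentile 99.82 of its matched random lists (-0.44 to 0.57), which argues against abundance and span of its members as the cause. Members that vary together between libraries for any reason stay open, since the adjusted p was 0.831 with an estimated correlation and 0.587 without hypoxia replicate 1. Hypoxia itself, as the designed difference, is untested as the cause beyond these comparisons.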

How the results depend on the processing

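The alternatives that sum all named transcripts of a gene, use nested names only, use the second naming score or test every transcript were chosen after seeing the data. The count of 0 genes past the adjusted threshold in edgeR (748 at an unadjusted p under 0.05) was also 0 with RLE factors, without the filter, without the 10 most abundant genes, with nested names only and with the second naming score. It was 213 with DESeq2 (60 higher, 153 lower), 11 with limma-voom, 2 with the H tables alone, 4 with the L tables alone, 1 with transcripts summed and 20 of 110278 transcripts, all lower, when every transcript was tested. Leaving out 1 library gave 0 to 140 genes, with 36 without hypoxia replicate 1 and 140 without hypoxia replicate 2. With the replicate number as a block it was 4 (2 higher, 2 lower), and the deviations of same-numbered libraries correlated at 0.0491 over only 2 pairs, so the numbers are not shown to pair the libraries. The count of 2 lists was 6 with limma-voom, 1 with transcripts summed, 1 with nested names only, 0 with an estimated correlation, 0 with fry's test for change in one direction and 0 to 2 with 1 library left out. It stayed at 2 with the L tables alone, where cholesterol synthesis was not among them (adjusted p = 0.264). Cholesterol synthesis was also the list lost with transcripts summed and with nested names only (camera adjusted p = 0.118 and 0.139). The pseudogene share differed by -0.0329 percentage points with the L tables, against -0.0155. Of 1635 pairs of a named gene and an alternative, 1535 kept the direction and the side of the threshold, 73 kept the direction and passed it, and 27 changed sign. With the H tables these were IGF2BP1 (0.42) and CRK (-0.48), with the L tables APP (0.0707), with transcripts summed SPRED1 (0.0210) and APLP2 (0.0833), with limma-voom BIRC3 (-2.06), APP (0.00107) and APLP2 (0.0756), and with the block CRK (-0.0175) and BIRC3 (-1.355). With 1 library left out the log2 fold changes that changed sign ranged as follows: CRK -0.56 to 0.51, ITGA5 -0.14 to 1.34, SDHA -0.65 to 2.55, NDUFS1 -1.82 to 0.0947, XBP1 -4.26 to 0.00894, PHGDH -2.70 to 2.17, BIRC3 -9.29 to 3.41, SREBF2 -0.14 to 1.57, APP -0.24 to 0.14, AHNAK -0.17 to 1.29, APLP2 -0.92 to 0.66, MBNL1 -0.22 to 0.36 and HSPG2 -0.30 to 1.14. The cause of these differences was not tested. The filter at a mean of 50 counts removed no gene, and the alternatives on TPM (0 throughout) and on length (equal in all tables) were not run. No mitochondrial or ribosomal RNA was named, so none was left out by name with the most abundant genes. Reads from such RNA inside the span of another gene were not examined. At an equal 12643041 counts per library, 781 and 643 named genes were at 0 in hypoxia replicates 1 and 2, against 146 and 63 in normoxia.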

Other observations

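Cytosolic ribosomal protein genes were mostly lower in hypoxia, 42 of 61 tested members with a median log2 fold change of -0.36, but the list did not pass (camera adjusted p = 0.236). RPS25 was at 23.5 ± 1.83 CPM in hypoxia and 98.7 ± 5.99 in normoxia, RPL4 at 71.5 ± 34.2 and 188 ± 20.1, and RPL6 at 23.0 ± 5.12 and 93.1 ± 26.8 (mean ± SD, n = 2 for all values in this part). These genes have many processed pseudogenes, and RPL4 also hosts small nucleolar RNAs. Nuclear-encoded genes of the respiratory chain went both ways, 13 of 29 higher with a median of -0.21 (camera adjusted p = 0.763). ATP5F1B, a subunit of the ATP synthase, was at 70.3 ± 34.2 and 178 ± 71.6 CPM, NDUFS1 at 154 ± 126 and 227 ± 0.671, and UQCRC2 at 135 ± 46.1 and 65.6 ± 53.5. SDHA, a subunit of succinate dehydrogenase, was at 159 ± 181 CPM in hypoxia and 48.5 ± 27.8 in normoxia, so its hypoxia replicates disagreed.

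Extracellular matrix genes had 12 of 19 tested members higher with a median of 0.23 (camera adjusted p = 0.566), among them the protease MMP2 at 444 ± 266 and 203 ± 45.8 CPM, COL8A1 at 377 ± 27.9 and 214 ± 4.56, and LAMB1 at 753 ± 28.6 and 469 ± 24.96. LOX, lysyl oxidase, was at 51.9 ± 5.01 CPM in hypoxia and 115 ± 38.8 in normoxia. Of the cytoskeletal and adhesion genes 13 of 20 were higher with a median of 0.24 (camera adjusted p = 0.763). ACTN1 was at 501 ± 196 and 269 ± 29.1 CPM, ACTN4 at 590.0 ± 340.4 and 893 ± 42.8, TMSB4X at 183 ± 50.01 and 371 ± 224, and TUBA1B at 92.4 ± 101 and 187 ± 87.9, the last 2 with processed pseudogenes. Stress response genes had 3 of 11 higher (median -0.15, camera adjusted p = 0.763), with ATF4 at 35.4 ± 22.2 and 52.9 ± 13.5 CPM and log2 fold changes of -2.30 ± 2.05 for ATF3, -0.90 ± 1.596 for XBP1 and -1.23 ± 2.23 for PHGDH. Inflammatory genes had 5 of 8 higher (median 0.54, camera adjusted p = 0.763), with NFKB1 at 179.7 ± 13.8 and 99.5 ± 14.4 CPM and log2 fold changes of 2.53 ± 1.78 for RELB, -1.94 ± 2.02 for NFKB2 and 2.15 ± 2.59 for BIRC3. No member of these 6 lists passed, over all genes or adjusted over the list alone.

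Markers of other cell types that the cultures could hold were tested where they had a name. The lymphatic endothelial genes PROX1, at 131 ± 15.7 CPM in hypoxia and 228 ± 52.8 in normoxia, LYVE1, at 64.7 ± 29.2 and 129 ± 43.6, and PDPN, at 185 ± 117 and 200.4 ± 59.1, were recovered in all 4 libraries, and endothelial cells of lymphatic vessels also express FLT4. Markers of smooth muscle and pericytes were lower in level, with ACTA2 at 27.05 ± 17.3 and 16.65 ± 6.51 CPM, MYH11 at 0.571 ± 0.446 and 12.7 ± 3.04, and NOTCH3 at 0.208 ± 0.0665 and 8.30 ± 10.4. The fibroblast marker COL1A2 was at 10.7 ± 5.26 and 7.34 ± 4.66 CPM. Of the epithelial markers, EPCAM was at 0.217 ± 0.0356 and 2.38 ± 0.311, CDH1 at 1.01 ± 0.847 and 8.61 ± 0.197, KRT8 at 21.3 ± 11.4 and 32.6 ± 14.8, and KRT18 at 4.60 ± 6.17 and 10.5 ± 7.27. None of these markers passed the adjusted threshold.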
